A study of Homo sapiens with 52 samples.

How the data were processed

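Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed by the submitters in LNCaP95 cells, a prostate cancer cell line kept in medium with hormone-stripped serum. Cells carried a short hairpin RNA against GFP (shGFP, the control), against the androgen receptor splice variant ARv7 (shARv7) or against full-length androgen receptor (shARfl). They received 10 nM dihydrotestosterone (DHT) or the ethanol vehicle (ETOH) for 4 h. The series lists 52 samples. The deposited table used here has a column for 21 of them, which are 6 H3K27ac, 6 ARv7 antibody, 6 ARfl antibody and 3 FOXA1 libraries. The other 31 samples (inputs, HOXB13, an ARN20 antibody and parental cells) were not analysed here.

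BWA, SAMtools, MACS2 and the hg19 build are named in the submitters' processing notes, without versions or settings. Per the file headers, the deposited regions are peaks with merged names, and the authors gave each of the 7552 regions to cluster 1 (3284 regions) or cluster 2 (4268 regions). How the clusters were made is not given in the sources used here. The peak lists deposited by the authors carry a score column that is 0 in every row and was not used. The region widths ran from 200 to 1636 bp, with a median of 315.5 bp.

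The values deposited by the authors are signal on a natural log scale, as found from the values, since no header or label says so. After the log was undone as exp(value) - 1 and the result multiplied by the region width, 100% of the values in each of the 21 columns were whole multiples of a step, within 0.01 of a step. Without undoing the log, between 2.16% and 8.21% were. The step was the same for all libraries of an antibody and equals a scaling to 17989400 reads for H3K27ac, 34040834 for ARv7, 29086914 for ARfl and 16415375 for FOXA1. Multiples were more frequent at 75 bases, the step of a single 75-base read, than at other values nearby in all libraries except the ARfl library of shARfl cells in DHT. Values below 0 occurred, so the control had been subtracted before deposit. The recovered quantity is called net signal: ChIP coverage minus control coverage per base pair, in RPM. It is not a count, ChIP and control can no longer be separated, and the sequencing depth of each library is unknown. The median region held between 0.533 and 2.93 net reads per H3K27ac library, between 0.92 and 10.2 per ARv7 library, between 5.16 and 46.5 per ARfl library and between 12.5 and 23.7 per FOXA1 library, on the scaled depth, and this limits the precision of H3K27ac values for single regions.

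For each antibody with 6 libraries, log2(net signal + 1) was fitted in limma 3.58.1 under R 4.3.3 with shRNA and treatment as additive terms, no further scaling, a mean-variance trend and Benjamini-Hochberg adjustment over the 7552 regions at a threshold of 0.05. The added 1 is the offset of the deposited log scale. Because net signal lies mostly far below 1, a log2 fold change on this scale understates the change of the net signal. There was 1 library for each combination of shRNA and treatment. The 2 treatments therefore stood in for replicates of an shRNA contrast, and the difference between them was the error, with 2 residual degrees of freedom. The labels do not say that libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The design had foreseen a parental pair in the ARfl fit of DHT, which was not run. Library-wide changes are given as ratios of mean net signal. Their 95% intervals come from 2000 bootstrap draws of regions and cover the spread over regions only, not that between cultures. Clusters were compared with camera at a preset correlation of 0.01 and with an estimated correlation. FOXA1, with 3 libraries, was described by ratios and by the percentile of each cluster's median among 10000 random sets matched on mean FOXA1 signal. Library means of DHT and ETOH were compared by an exact two-sided permutation test, which did not use the matching of libraries by shRNA. Correlations were taken across regions, which are not independent replicates, and carry no p.

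Per the labels, the H3K27ac and FOXA1 libraries belong to 1 batch and the ARv7 libraries to another. The ARfl libraries of shARfl cells share the batch date of the ARv7 libraries, while those of shGFP and shARv7 cells carry another day and month. The labelled year of the latter grows by 1 from sample to sample, and they were treated as 1 batch. Coordinates are hg19, counted from 1. The reference gene table at hand is for another build, so regions were not tied to genes and the gene lists fixed beforehand were not assessed here. The rule for the regions to name was fixed before the data were examined. For each comparison, they are up to 10 in each direction with the largest log2 fold change among those that passed and had the same sign in every matched pair of libraries. Where none passed, they are the 5 highest and 5 lowest with a mean signal above the median. The text gives the leading ones of each list.

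The limma procedure was tested on simulated libraries with 200 of 7552 regions changed by a known amount, 1 draw per amount, so recovery varies from draw to draw. For shARv7 against shGFP, a log2 change of 0.4 was recovered in 59.5% of changed regions for H3K27ac, 100% for ARv7 and 32.5% for ARfl. For DHT against ETOH in ARfl, recovery was 0% at 0.4, 36% at 0.8 and 97% at 1.6. In the H3K27ac simulations, the most unchanged regions called were 10, beside 176 changed ones, for shARv7 against shGFP and 16, beside 181, for DHT against ETOH. No simulation without changed regions was run. Noise was drawn independently for each region, whereas camera estimated a correlation of 0.518 between cluster 2 regions for H3K27ac. In the real ARfl fit of DHT 4201 regions rose, far more than 200. The recovery and false calls therefore hold for the simulated setting and may differ in these data. Alternatives were median centring, added constants of 5 and 0.2 (net signal raised to at least -0.1 for the latter), removal of the lowest 25% of regions by mean signal, leaving out each library, and a generalised log with constant 0.05, the last chosen after seeing the data. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used for the other steps.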

Results

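ChIP-seq signal for acetylated histone H3 lysine 27 (H3K27ac, a mark of active promoters and enhancers), ARv7, full-length androgen receptor (ARfl) and FOXA1 was compared over 7552 regions in LNCaP95 prostate cancer cells. ARv7 is a splice variant of the androgen receptor that lacks the ligand-binding domain, and FOXA1 is a pioneer factor that opens chromatin for the receptor. H3K27ac, ARv7 and ARfl were each measured in 6 libraries, from shGFP, shARv7 and shARfl cells in vehicle (ETOH) and DHT. FOXA1 was measured in 3 libraries, all in ETOH. Each combination had 1 library, so no value below has a replicate of its own. Values are net signal, which is coverage above control (RPM per base pair) on a scale common to all libraries of an antibody, and intervals are 95% bootstrap intervals over regions.

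**Figure D1:**
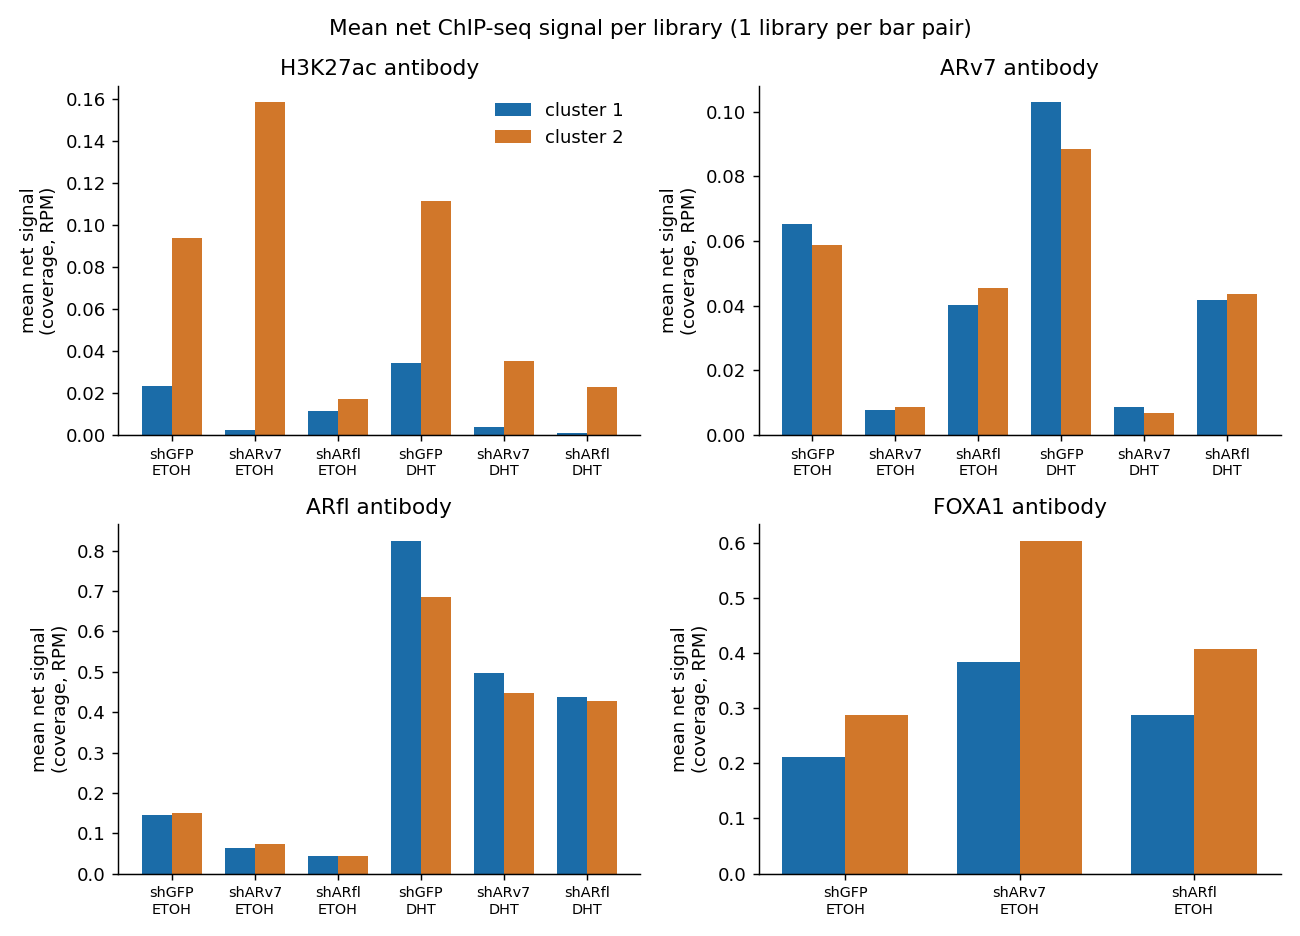
Mean net signal (vertical axis, coverage in RPM, a separate linear scale for each antibody) over the 3284 cluster 1 and 4268 cluster 2 regions in each of the 21 libraries, with each bar standing for 1 library. ARv7 bars are lowest in shARv7 cells, ARfl bars are highest in DHT, and the cluster 2 H3K27ac bar reaches 0.158 in shARv7 cells in ETOH against 0.0351 in DHT.

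The ARv7 antibody libraries first asked whether the targeted protein left the chromatin in shARv7 cells. Signal over all regions was 0.00831 in shARv7 cells against 0.0615 in shGFP cells in ETOH, a ratio of 0.135 (0.125 to 0.146). In DHT it was 0.00762 against 0.0947, a ratio of 0.0805 (0.0736 to 0.087). Of the 7552 regions, 1672 fell at the limma threshold, 843 of them in cluster 1 and 829 in cluster 2, and 0 rose, where 2 were higher at an unadjusted p under 0.05. Signal was lower in both matched pairs in 75.9% of regions, where even and independent signs would give 25%. A shift common to a whole library also raises this share, so it says nothing on single regions. The region with the largest fall, merge_peak_21 on chromosome 1 from 9496265 to 9496769, had a log2 fold change of -0.86 (SE 0.13, adjusted p = 0.00501). Its net signal was 1.63 in shGFP cells and 0.227 in shARv7 cells in DHT. The next was merge_peak_1379 on chromosome 11 from 80493596 to 80494144, with -0.70 (SE 0.108, adjusted p = 0.00501). After median centring, which removes a shift of equal size on the log2 scale, 83 regions were lower and 4 higher. With the added 1, a factor common to all regions moves regions of high signal more, and centring does not remove it. Without the shARv7 ETOH or the shARv7 DHT library 0 regions passed, and without the shGFP ETOH library 2889 did.

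ARv7 antibody signal was also lower in cells in which full-length receptor had been targeted. In shARfl cells it was 0.0432 in ETOH and 0.0429 in DHT, which is 0.702 (0.686 to 0.719) and 0.453 (0.441 to 0.464) of the shGFP values. In limma 2 regions fell and 0 rose, where at an unadjusted p under 0.05 1301 were lower and 72 higher. They were merge_peak_21, with a log2 fold change of -0.77 (SE 0.13, adjusted p = 0.0441), and merge_peak_408 on chromosome 1 from 160101788 to 160102115, with -0.33 (SE 0.0541, adjusted p = 0.0441). On a generalised log scale, which follows ratios more closely, 250 regions were lower and 2 higher. With a constant of 0.2 in place of 1 these counts were 223 and 1. With a constant of 5, with median centring, or without the lowest 25% of regions, 0 passed. Without 1 library, the count was 0 for either shARv7 library, 1409 for shGFP ETOH, 205 for shGFP DHT and 68 for shARfl ETOH.

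DHT was compared with ETOH to ask how the ligand changes occupancy by each receptor form. For the ARv7 antibody, signal in DHT was 1.54 times (1.51 to 1.57) that in ETOH in shGFP cells, 0.917 times (0.821 to 1.03) in shARv7 cells and 0.993 times (0.969 to 1.02) in shARfl cells. No region passed in limma, where 542 had an unadjusted p under 0.05, 422 of them higher in DHT. The fit averages the shRNAs and takes the difference between them in the response to DHT as error. With unlike ratios, the lack of calls therefore does not show that DHT changed no region in shGFP cells. Among regions with a mean signal above the median, none of which passed, the highest was again merge_peak_21, with a log2 fold change of 0.41 (SE 0.106, adjusted p = 0.654), and the lowest was merge_peak_662 on chromosome 1 from 222796249 to 222796576, with -0.13 (SE 0.04, adjusted p = 0.654). On the generalised log scale 12 regions were higher. Leaving out the shARfl ETOH library gave 7 regions, and leaving out the shARfl DHT library gave 12.

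ARfl antibody signal rose with DHT at 4201 of the 7552 regions (55.6%). Mean signal was 0.746 in DHT against 0.148 in ETOH in shGFP cells, a ratio of 5.03 (4.89 to 5.16). The ratio was 6.78 (6.57 to 7.02) in shARv7 cells and 9.87 (9.62 to 10.1) in shARfl cells. Of the regions that rose at the limma threshold, 1925 lay in cluster 1 and 2276 in cluster 2, and 1 region fell. Signal was higher in all 3 matched pairs in 76.9% of regions, where even and independent signs would give 12.5%. A shift common to a whole library also raises this share, so it says nothing on single regions. The largest rise was at merge_peak_21, from 0.908 to 16.7 in shGFP cells and from 0.388 to 9.45 in shARv7 cells, with a log2 fold change of 2.58 (SE 0.386, adjusted p = 0.0059). The second, merge_peak_1531 on chromosome 11 from 129895272 to 129895619, went from 0.312 to 11.2 in shGFP cells, with a log2 fold change of 2.27 (SE 0.423, adjusted p = 0.0059). The single region that fell was merge_peak_3 on chromosome 1 from 1310576 to 1310825, with -0.37 (SE 0.151, adjusted p = 0.0454), a call that held in 8 of 12 alternatives.

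The 3 library means were 0.549 ± 0.171 (SD, n = 3) in DHT and 0.0871 ± 0.0546 (SD, n = 3) in ETOH. An exact two-sided permutation test of them gave p = 0.1, the smallest that 3 libraries against 3 allow. It did not use the matching of libraries by shRNA. Each SD spans 3 different shRNAs, and for ARfl the shARfl pair is from another batch, so it is not a spread of replicates. The same exact test gave p = 0.6 for H3K27ac (0.0377 ± 0.0352 in DHT and 0.0562 ± 0.0384 in ETOH, SD, n = 3 each) and p = 1 for ARv7 (0.0484 ± 0.0438 and 0.0377 ± 0.027, SD, n = 3 each). DHT shifted the median of the log2 values by 0.29, and relative to that shift 148 regions were higher and 528 lower. With the added 1, a factor common to all regions moves weak regions less, so these counts do not show changes particular to single regions. Without the shARfl pair, which belongs to another batch, 4147 regions were higher and 27 lower. Without 1 library the count was 1 for shGFP ETOH, 1 for shARv7 ETOH, 6 for shGFP DHT and 8 for shARv7 DHT.

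The ARfl antibody libraries were next compared between knock-downs, beginning with the targeted protein. In shARfl cells ARfl signal was 0.0438 in ETOH and 0.432 in DHT, which is 0.295 (0.287 to 0.304) and 0.579 (0.56 to 0.599) of the shGFP values. No region passed in limma, where 1329 had an unadjusted p under 0.05, 1157 of them lower. On the generalised log scale 696 were lower and 3 higher. Among regions with a mean signal above the median, none of which passed, the lowest was merge_peak_5673 on chromosome 5 from 133802102 to 133802397, with a log2 fold change of -1.92 (SE 0.486, adjusted p = 0.255). Its net signal in DHT was 6.37 in shGFP cells and 0.0733 in shARfl cells. In contrast, merge_peak_3119 on chromosome 18 from 65896026 to 65896992 had a net signal of 6.91 in shARfl cells in DHT against 0.619 in shGFP cells, with a log2 fold change of 1.04 (SE 0.499, adjusted p = 0.287), and -0.22 without the shARfl DHT library. The shARfl and shGFP libraries come from different batches, so the batch and the knock-down cannot be told apart here. Without the shARfl ETOH library 1084 regions were higher and 1903 lower, without shGFP ETOH 23 and 143, and without shARfl DHT 0 and 102, while 1 was lower without any of the others.

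In shARv7 cells, within a single batch, ARfl signal was 0.0691 in ETOH and 0.469 in DHT, which is 0.466 (0.456 to 0.475) and 0.629 (0.623 to 0.635) of the shGFP values. Signal was lower in both pairs in 61.9% of regions and higher in both in 6.71%, where even and independent signs would give 25% each. A shift common to a whole library also moves these shares, so they say nothing on single regions. The median of the log2 values shifted by -0.11 against shGFP cells, and relative to that shift 0 regions passed as well. No region passed in limma, where 232 had an unadjusted p under 0.05, 229 of them lower. That fit also held the shARfl libraries of the other batch, which are not part of the contrast but enter its error. Of those with a mean signal above the median, none of which passed, the lowest was merge_peak_3961 on chromosome 20 from 57875048 to 57875250, with a log2 fold change of -0.94 (SE 0.378, adjusted p = 0.886), and its net signal in DHT was 4.58 in shGFP cells and 1.06 in shARv7 cells. The highest was merge_peak_5592 on chromosome 5 from 114038416 to 114038806, with 0.25 (SE 0.218, adjusted p = 0.886). Without the shARfl ETOH library 335 regions were lower and 2 higher, without shARfl DHT 231 and 1, and without any of the others 1 or 2 passed.

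H3K27ac was compared to ask whether active chromatin changed with either knock-down. Mean signal in shARv7 cells was 0.0906 against 0.0632 in shGFP cells in ETOH, a ratio of 1.43 (1.4 to 1.46), but 0.0215 against 0.078 in DHT, a ratio of 0.276 (0.265 to 0.287). In shARfl cells it was lower in both treatments, with ratios of 0.234 (0.221 to 0.247) and 0.173 (0.162 to 0.183). At the limma threshold 1 region, in cluster 2, rose and 5, in cluster 1, fell with shARv7. The fit averages the treatments and takes the difference between them as error. With opposite ratios in ETOH and DHT, the low count therefore does not show that few regions changed. The same error enters the other H3K27ac comparisons of shRNAs. The region that rose was merge_peak_6178 on chromosome 6 from 142742460 to 142742659, with a log2 fold change of 0.26 (SE 0.063, adjusted p = 0.0485). This call held in 3 of 11 alternatives. It was lost with a constant of 0.2 (adjusted p = 0.0838), without the lowest 25% of regions (0.133), on the generalised log scale (0.372) and without any single library except shARv7 DHT. The largest falls were at merge_peak_1031 on chromosome 10 from 79258738 to 79258951, with -0.29 (SE 0.0557, adjusted p = 0.00165), and at merge_peak_2097 on chromosome 13 from 93852901 to 93853202, with -0.21 (SE 0.0475, adjusted p = 0.0157). These calls held in 9 and 6 of 11 alternatives. Without the shGFP DHT library their log2 fold changes shrank to -0.18 and -0.11. The other 3 were merge_peak_2711, merge_peak_263 and merge_peak_4644. In all 5 regions that fell, net signal was below 0 in both shARv7 libraries, so control exceeded ChIP there. Without the shARv7 ETOH library 82 regions were lower and 1 higher, without shARv7 DHT 33 were higher and 10 lower, and the count was 16 without shGFP ETOH, 3 without shARfl ETOH and 1 without shARfl DHT.

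With shARfl, 16 regions fell, 10 in cluster 1 and 6 in cluster 2, and 1 rose. The largest fall was at merge_peak_2204 on chromosome 14 from 30365075 to 30365284, with a log2 fold change of -0.76 (SE 0.196, adjusted p = 0.0495). Its net signal was 1.31 in shGFP cells and 0.459 in shARfl cells in ETOH, and 1.64 and 0.455 in DHT. Next was merge_peak_1484 on chromosome 11 from 114034643 to 114035001, with -0.59 (SE 0.15, adjusted p = 0.0495). Its neighbour merge_peak_1483, from 114033519 to 114033919, fell by 0.23 (SE 0.0585, adjusted p = 0.0495). The region that rose was merge_peak_375 on chromosome 1 from 145020568 to 145020938, with 0.19 (SE 0.0466, adjusted p = 0.0495), although its net signal was below 0 in 5 of the 6 libraries. The calls held in 3 of 11 alternatives for merge_peak_2204, 5 of 11 for merge_peak_1484 and 4 of 10 for merge_peak_375. After median centring, or without the lowest 25% of regions, 0 passed. Without 1 library the count was 920 for shARv7 ETOH, 949 for shARv7 DHT, 50 for shGFP ETOH, 2 for shARfl DHT, 1 for shGFP DHT and 0 for shARfl ETOH.

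In the direct comparison of shARv7 with shARfl, 4 regions were higher in shARv7 cells, all in cluster 2. They were merge_peak_1940 on chromosome 12 from 125399190 to 125399494, with a log2 fold change of 0.42 (SE 0.0828, adjusted p = 0.0011), and merge_peak_6178, with 0.33 (SE 0.063, adjusted p = 0.0011), followed by merge_peak_4873 and merge_peak_467. Apart from merge_peak_1940, their net signal was below 0 in both shARfl libraries. The calls held in 7 of 11 alternatives for merge_peak_6178 and 5 of 11 for merge_peak_4873. The change of merge_peak_1940 did not have the same sign in both pairs, so it lies outside the naming rule and was chosen after its values were seen. Without the shARv7 ETOH library the direction turned, with 1 region higher and 5 lower, and the adjusted p of merge_peak_6178 was 0.931. Without the shARv7 DHT library 1218 regions were higher and 19 lower, and without shARfl ETOH 1 was higher.

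H3K27ac in DHT was 1.23 times (1.21 to 1.26) that in ETOH in shGFP cells, 0.237 times (0.229 to 0.246) in shARv7 cells and 0.91 times (0.849 to 0.98) in shARfl cells. With DHT against ETOH, 1 region rose and 3 fell. Here too the difference between shRNAs in the response to DHT enters as error. With such unlike ratios, the low count does not show that few regions changed in cells of a given shRNA. The region that rose was merge_peak_3259 on chromosome 2 from 18981676 to 18981961, with 0.14 (SE 0.0341, adjusted p = 0.0498). Its net signal was 0 or below in the 3 ETOH libraries, and the call held in 0 of 10 alternatives. Those that fell were merge_peak_1071 on chromosome 10 from 98300125 to 98300370, with -0.23 (SE 0.0464, adjusted p = 0.00169), merge_peak_1940, with -0.29 (SE 0.0676, adjusted p = 0.0498), and merge_peak_7309 on chromosome 9 from 140222750 to 140222983, with -0.20 (SE 0.0357, adjusted p = 9.46e-05). These last 2 lie outside the naming rule and were chosen after their values were seen. For merge_peak_7309, net signal was below 0 in 4 of the 6 libraries, and -0.212 in shGFP cells in DHT was the lowest value of that library, so control exceeded ChIP there. For merge_peak_1071 it was -0.151 in that library. The call of merge_peak_1071 held in 8 of 11 alternatives and was lost on the generalised log scale (adjusted p = 0.284). Without 1 library the count was 2 for shGFP ETOH, 2 for shARfl ETOH, 8 for shARv7 ETOH and 7 for shARv7 DHT.

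Beyond single regions, the H3K27ac response to shARv7 in ETOH was opposite in the authors' 2 region clusters. Cluster 2 signal was 0.158 in shARv7 cells against 0.0939 in shGFP cells, a ratio of 1.69 (1.66 to 1.72), while cluster 1 signal was 0.00254 against 0.0234, a ratio of 0.108 (0.055 to 0.161). In DHT both were lower in shARv7 cells, with ratios of 0.315 (0.304 to 0.326) in cluster 2 and 0.111 (0.0804 to 0.141) in cluster 1. With shARfl in ETOH the ratios were 0.184 (0.169 to 0.198) in cluster 2 and 0.497 (0.446 to 0.553) in cluster 1. Of 231 single libraries and differences of libraries, the shARv7 minus shARfl difference of H3K27ac in ETOH told the clusters apart best, with an area under the curve of 0.965. Without the ETOH H3K27ac libraries the best reached 0.692. The clusters are thus not independent evidence for the H3K27ac response in ETOH.

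The clusters appear to be sorted on H3K27ac in ETOH, and each H3K27ac fit includes those libraries, so the p-values of the 4 H3K27ac cluster differences below are not evidence of a response. Camera placed cluster 2 above cluster 1 for H3K27ac with shARv7 against shGFP, by 0.03 on the log2 scale (adjusted p = 2.64e-08), and below it with shARfl, by -0.07 (adjusted p = 3.02e-08). Cluster 2 also stood above cluster 1 in shARv7 against shARfl, by 0.10 (adjusted p = 2.03e-47), and below it in DHT against ETOH, by -0.04 (adjusted p = 2.07e-05). With an estimated correlation, which was 0.518, none of the 4 passed, and the adjusted p was 0.758 for each. For the 6 comparisons of the ARv7 and ARfl antibodies, cluster 2 differed from cluster 1 by between -0.05 and 0.04, and adjusted p ran from 0.0612 to 0.461 at the preset correlation. Over regions above the median signal, the H3K27ac difference with shARfl no longer passed (-0.06, adjusted p = 0.207), while those of ARv7 with shARfl (0.03, adjusted p = 0.00296), ARfl with shARv7 (0.04, adjusted p = 0.0394) and ARfl with DHT (-0.07, adjusted p = 0.0394) did. These calls used the preset correlation. With an estimated one, which was 0.0787 for ARv7 and 0.0378 for ARfl and was run over all regions only, adjusted p was 0.758 for these 3 comparisons too.

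**Figure D2:**
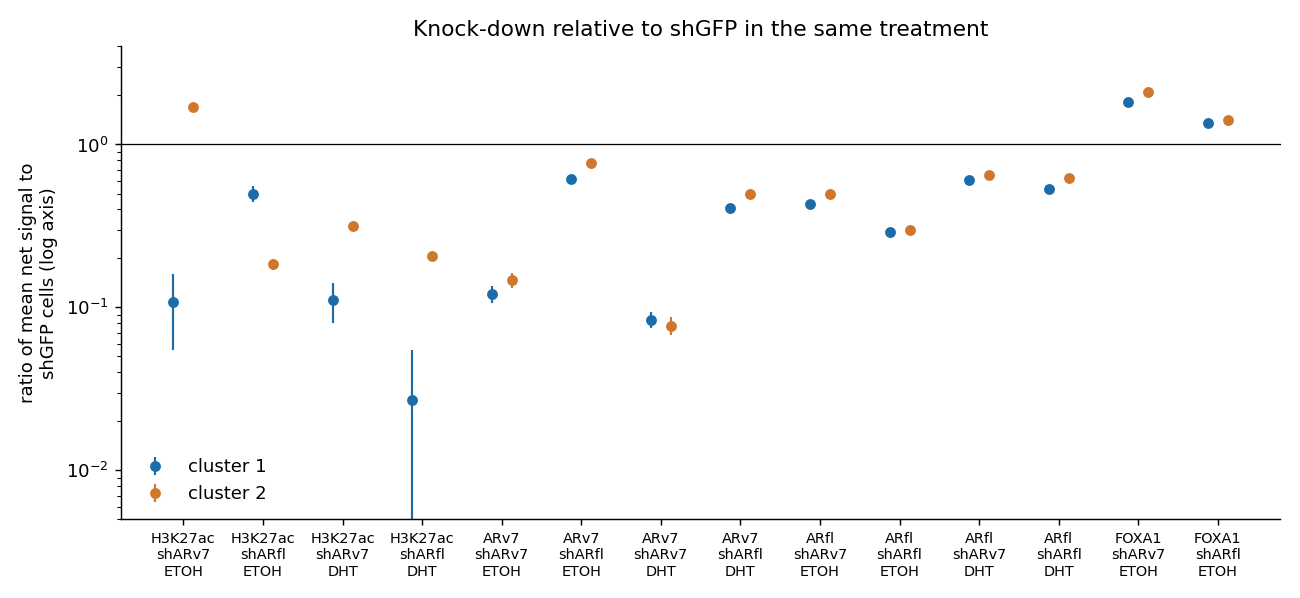
Ratio of mean net signal in knock-down cells to that in shGFP cells of the same treatment (log axis), for cluster 1 and cluster 2 regions. Points are single library pairs and bars are 95% bootstrap intervals over regions, with the bar that reaches below 0 drawn to the edge of the axis; FOXA1 ratios, with no scaling between libraries, are above 1, and the cluster 2 H3K27ac ratio in shARv7 cells in ETOH is 1.69.

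FOXA1 signal, measured in ETOH, was higher in both knock-downs than in shGFP cells when libraries were not scaled to each other. Over all regions it was 0.508 in shARv7 cells and 0.356 in shARfl cells against 0.255 in shGFP cells, ratios of 1.99 (1.97 to 2.01) and 1.4 (1.38 to 1.41). In shARv7 cells the ratio was 2.09 (2.07 to 2.12) in cluster 2 and 1.81 (1.78 to 1.84) in cluster 1. The median log2 change of cluster 2, 0.24, lay above that of all 10000 matched random sets (central 95% from 0.219 to 0.228), and that of cluster 1, 0.11, lay below all of them (0.13 to 0.14). In shARfl cells the cluster medians, 0.08 and 0.05, lay at percentiles 13.2 and 77.4. With 1 library per shRNA no test of the overall increase was possible. Scaled to the total signal over all regions, the ratio was 1.05 in cluster 2 and 0.91 in cluster 1 in shARv7 cells, and 1.01 and 0.974 in shARfl cells. The clusters together hold all regions, so this scaling must put unlike cluster ratios on opposite sides of 1. The values below 1 in cluster 1 therefore do not show a fall. With median centring the ratios were 1.1 and 0.951, and 1.13 and 1.08. The labels list 1 input per shRNA and treatment for the batch of H3K27ac and FOXA1, and do not say which input each library used. The FOXA1 differences between clusters are therefore not taken as independent of H3K27ac in ETOH. HOXB13 was not analysed here.

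Co-occupancy was described by correlation across regions. ARv7 and ARfl antibody signals in shGFP cells had a Spearman correlation of 0.281 in ETOH and 0.635 in DHT. In DHT the correlation was 0.0879 in shARv7 cells and 0.307 in shARfl cells. The ARv7 library of shARv7 cells in DHT held 0.92 net reads in the median region and was at or below control in 40.7% of regions. It correlated at only 0.179 with the ARv7 library of shGFP cells in DHT. ARfl signal of shGFP cells was also weaker in ETOH (0.148) than in DHT (0.746). Low correlations can come from weak signal alone, so they do not show a loss of co-occupancy. FOXA1 in shGFP cells in ETOH correlated with H3K27ac at 0.197, with ARfl at 0.11 and with ARv7 at 0.0736. As a reference for how far libraries of the same antibody go together, ARfl in DHT correlated at 0.897 between shGFP and shARv7 cells, FOXA1 at 0.882 between the same cells in ETOH, and, between ETOH and DHT in shGFP cells, H3K27ac at 0.637 and ARv7 at 0.45. The last is below the 0.635 between the ARv7 and ARfl antibodies in DHT. Of the 1672 regions that lost ARv7 antibody signal with shARv7, 1454 (87%) were among the 4201 that gained ARfl antibody signal with DHT. Both lists favour regions of high signal, and ARfl signal in shGFP cells in DHT was 1.63 at the 1672 regions against 0.494 at the others. The overlap was not compared with regions matched on signal.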

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

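The tests of weak regions, of ratios by cluster and by loss of ARv7 signal, and of the area under the curve were chosen only after the results were seen; the other tests of explanations were fixed before theirs. Apart from ARfl signal in shARv7 cells and the splits of libraries, each result below had an effect that went opposite ways in 2 groups, with both bootstrap intervals on their own side of 1. Each group is 1 library pair, so none of these differences was tested against replicates.

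H3K27ac signal in shARv7 cells was 1.4328 times that of shGFP cells in ETOH and 0.276 times in DHT, and in cluster 2 the ratios were 1.6872 and 0.315. A separate recovery of chromatin in each library, technical or not, would multiply all regions alike. Between the 25% of regions with the highest and the 25% with the lowest FOXA1 signal, the ratios differed 1.4-fold (1.217 to 1.653) in DHT and 1.343-fold (1.246 to 1.454) in ETOH, both short of the bound set beforehand against a factor. By the tests chosen afterwards alone, the ratio in DHT differed 2.848-fold (2.23 to 3.956) between cluster 2 and cluster 1. The cluster 1 mean in shARv7 cells is near 0 there, with 47.3% of regions at or below control. Where ARv7 signal was lost, the ratio in DHT was 0.6623 times (0.5985 to 0.7286) that elsewhere. This is just past the bound, and its interval reaches back over it. These intervals leave out 1, which goes against 1 factor per library as the whole cause in DHT. The planned test fell short and these tests were chosen afterwards, so they do not settle it. In ETOH the value by loss of ARv7 signal was 0.7776 (0.7333 to 0.8234), short of the bound set against a factor though it leaves out 1. The cluster value of 15.6 (10.6 to 31.4) is circular because the clusters appear sorted on those libraries. Recovery and an effect of the knock-down can therefore not be told apart in ETOH. A factor joined to uneven control subtraction, and a biological effect, stay open and untested in both treatments.

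Clusters 1 and 2 moved apart in H3K27ac with shARv7, and the clusters could have been sorted on chance values of the same libraries. Membership by chance alone is argued against by the DHT libraries, for which the labels list inputs of their own: H3K27ac told the clusters apart there with an area under the curve of 0.6922 (0.6813 to 0.7044) in shGFP cells, 0.665 in shARv7 cells and 0.629 in shARfl cells. These values show that cluster 2 holds regions of higher H3K27ac level. They do not show that the clusters moved apart with shARv7. How much of the separation in ETOH comes from sorting stays open, since regions 1 to 10 kb apart shared a cluster 7.279 percentage points more often than with permuted cluster numbers, but 8 of 10000 permutations gave as much, short of the bound set beforehand, and among low-signal regions the difference was -3.46 points. Weak regions might also lose more in any weak library. In DHT the cluster 2 ratio over the cluster 1 ratio was 2.848 in shARv7 cells and 7.636 in shARfl cells. The interval of the latter ran from -27.7 to 53.9 because the cluster 1 signal reaches 0. In ETOH the value in shARfl cells was 0.369 (0.325 to 0.424). It decides nothing here, because the clusters appear sorted on that library too. How the clusters were made and which input each library used is not stated, FOXA1 in ETOH decides nothing here because it may share inputs with H3K27ac, and an effect of the knock-down stays open.

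ARfl antibody signal was lower in shARv7 cells in both treatments, which could come from an antibody that also binds ARv7. The ratio in ETOH would then be lowest where ARv7 signal is highest, but it was 1.069 times (1.012 to 1.132) as high in the highest as in the lowest 25% of regions by ARv7 signal of shARfl cells, which is not far enough above 1 for the bound set beforehand. In contrast, at the regions that lost ARv7 signal, chosen by their outcome in the ARv7 libraries, the ratio was 0.36 in ETOH against 0.527 elsewhere, 0.6839 times (0.6498 to 0.7183) as high, and 0.607 against 0.649 in DHT, which goes with such binding and against a single recovery factor per library without reaching the bound set against the latter. Between the 25% sets the ratio in DHT was even (0.9948, 0.9674 to 1.022), as a single factor would give. The 2 explanations and a loss of ARfl binding cannot be told apart, and the loss stays open and untested.

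ARv7 antibody signal in cluster 2 was 1.5063 times as high in DHT as in ETOH in shGFP cells, but 0.791 times in shARv7 cells and 0.961 times in shARfl cells. The ratio in shARv7 cells sets 0.00683 against 0.00864, with 42.2% and 38.6% of regions at or below control, so it rests on signal near 0. H3K27ac signal over all regions was 1.2336 times as high in DHT in shGFP cells, against 0.237 in shARv7 and 0.91 in shARfl cells. In cluster 1 the H3K27ac ratio was 1.474 in shGFP and 0.0805 (-0.00894 to 0.164) in shARfl cells. The shARfl mean in DHT was 0.000938 there, with 50.9% of regions at or below control, so this ratio too rests on signal near 0. In cluster 2 it was 1.1874 in shGFP cells and 1.3409 in shARfl cells, against 0.222 in shARv7 cells.

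Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. For DHT against ETOH, the ARfl count was 4202 and the highest of the other splits gave 70, so 1 of the 10 splits gave as many. For H3K27ac the real count was 4 and the highest other 465, with 7 of 10 splits at or above the real count. For ARv7 they were 0 and 511, with 10 of 10, a share fixed in advance by a real count of 0. Since shRNA stayed in the fit, a split that divides 1 shRNA pair is informed by that pair alone. Splits dividing the same pair repeat the same count, and the shares above include these repeats. The 465 regions thus rest on the DHT and ETOH libraries of shARv7 cells, and the 511 on those of shGFP cells, which points to a structure of the samples. With 1 library against 1, treatment, recovery and noise are not separated in it.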

How the results depend on the processing

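The generalised log was chosen only after the data were seen; the other settings were planned. Apart from single libraries left out, 65 of 102 alternative values of the comparisons were classed as unchanged, which does not show that the values held. For cluster differences it means the same sign and the same side of the adjusted p threshold, whatever the size. The H3K27ac shARv7 difference of 0.02539 was thus classed as unchanged at 0.0591 (regions above the median signal) and 0.3673 (generalised log). The H3K27ac shARv7 ratio of 0.794 was so classed at 0.276 in DHT alone. For counts it means a similar size, 0 against 0 included, and not the same regions or directions. With a constant of 5, H3K27ac DHT against ETOH had 0 higher and 3 lower, and with 0.2, H3K27ac shARv7 against shGFP had 0 higher and 4 lower. The cause of the changes below was not tested. With median centring, the counts were 0 for H3K27ac shARfl against shGFP, 1 for H3K27ac DHT against ETOH, 87 (4 higher, 83 lower) for ARv7 shARv7 against shGFP, 0 for ARv7 shARfl against shGFP and 676 (148 higher, 528 lower) for ARfl DHT against ETOH; for H3K27ac shARv7 against shGFP the split was 2 higher and 3 lower, and for shARv7 against shARfl 2 and 1. With a constant of 5 they were 6 for H3K27ac shARfl and 0 for ARv7 shARfl, and with 0.2 they were 28 for H3K27ac shARfl, 8 for H3K27ac shARv7 against shARfl, 1 for H3K27ac DHT and 224 for ARv7 shARfl. Without the lowest 25% of regions they were 2 for H3K27ac shARv7 against shGFP, 0 for shARfl, 2 for shARv7 against shARfl, 1 for DHT, and 0 for ARv7 shARfl. With the generalised log they were 3 for H3K27ac shARv7 against shGFP, 3 for shARfl, 1 for shARv7 against shARfl, 0 for DHT, 252 for ARv7 shARfl, 12 for ARv7 DHT and 699 (3 higher, 696 lower) for ARfl shARfl. Leaving out 1 library, which leaves 1 residual degree of freedom and assumes a lone library to vary like the others, gave 1 to 83 regions for H3K27ac shARv7, 0 to 949 for shARfl, 1 to 1237 for shARv7 against shARfl (1 higher and 5 lower without shARv7 ETOH) and 2 to 8 for DHT. It gave 0 to 2889 for ARv7 shARv7, 0 to 1409 for ARv7 shARfl and 0 to 12 for ARv7 DHT, and 1 to 337 for ARfl shARv7, 1 to 2987 for ARfl shARfl and 1 to 4234 for ARfl DHT. The cluster differences in H3K27ac, 0.02539, -0.07431, 0.0997 and -0.04021 for shARv7, shARfl, shARv7 against shARfl and DHT, no longer passed with an estimated correlation (adjusted p = 0.758, as for all 10 comparisons). Over regions above the median signal, at the preset correlation, the difference was -0.05761 for H3K27ac shARfl (adjusted p = 0.207), 0.02964 for ARv7 shARfl (adjusted p = 0.00296), 0.0443 for ARfl shARv7 and -0.07262 for ARfl DHT (adjusted p = 0.0394 for both). The H3K27ac ratio of shARv7 to shGFP cells over both treatments was 0.794, and 1.433 in ETOH alone. The FOXA1 cluster 2 ratios were 1.051 with total scaling and 1.098 with median centring in shARv7 cells, and 1.015 and 1.127 in shARfl cells. Those of cluster 1 were 0.91 and 0.951 in shARv7 cells and 0.974 and 1.08 in shARfl cells. Total scaling puts unlike cluster ratios on opposite sides of 1 by construction. The ARv7 and ARfl correlation in DHT was 0.6901 by Pearson. Of the named regions, merge_peak_7253 ranged from -0.1494 without the shARv7 DHT library to 0.6358 without shARv7 ETOH, and merge_peak_3119 from -0.2191 to 2.295 and merge_peak_5473 from -0.1193 to 1.484 without shARfl DHT and shARfl ETOH. Count tests, input subtraction and the parental pair were not run, since the values are net signal and no such columns were used here, and restricting to both clusters moves nothing, since they hold all 7552 regions. The low net coverage of H3K27ac limits what single regions can show.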

Other observations

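The 1672 regions that lost ARv7 antibody signal with shARv7 were chosen by their outcome in the ARv7 libraries, so the following describes them in other libraries. The H3K27ac ratios of shARv7 to shGFP cells and that of ARfl in ETOH were also set against a recovery factor above (0.6623, 0.7776 and 0.6839), and the other values were not tested. H3K27ac in shGFP cells was 1.55 times (1.49 to 1.62) as high in DHT as in ETOH at these regions and 1.14 times (1.11 to 1.17) at the other 5880. In shARv7 cells H3K27ac was 0.202 times (0.185 to 0.219) the shGFP value in DHT at these regions and 0.305 times (0.291 to 0.318) elsewhere, and in ETOH 1.17 times (1.11 to 1.23) against 1.51 times (1.47 to 1.54). The FOXA1 ratio of shARv7 to shGFP cells was 1.69 (1.64 to 1.73) against 2.07 (2.05 to 2.09). The ARfl antibody ratio in ETOH was 0.36 (0.344 to 0.377) against 0.527 (0.516 to 0.539). Of these regions 50.4% lay in cluster 1, against 41.5% of the others.

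Across regions, which are not independent replicates, the FOXA1 change with shARv7 had a Spearman correlation of 0.314 with the H3K27ac change in ETOH and of -0.0524 with that in DHT. With the ARfl change it was 0.137 in ETOH and 0.256 in DHT, and with the ARv7 change 0.101 and 0.191. For shARfl, the FOXA1 and H3K27ac changes correlated at -0.0394 in ETOH and -0.102 in DHT. Whether the ETOH libraries of FOXA1 and H3K27ac had the same inputs subtracted is not stated, so their changes in ETOH are not taken as independent. The lowest net signal in the table was -0.854, at merge_peak_7309 in the ARfl library of shARfl cells in ETOH, where control coverage exceeded that of the ChIP.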
